A study of Mus musculus with 21 samples.

How the data were processed

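RNA from skin, liver and epididymal fat of male C57Bl6/J mice was measured on 21 single-colour Agilent mouse arrays. The mice lacked JNK1, the kinase encoded by *Mapk8* (knockout, KO), or were wild type (WT). Per the labels, they ate a high-fat diet from 5 to 44 weeks and were 45 weeks old, and Cy3-labelled cRNA was made from 0.2 ug of total RNA. The files hold 4 KO and 3 WT skin arrays, 3 and 3 liver arrays, and 4 and 4 fat arrays, whereas the series text speaks of quadruplicates for each condition. The labels do not say whether each array is a different mouse or which arrays share a mouse, so every p-value measures the spread between these samples only.

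Per the file headers, each scanner file gives spot intensity from Agilent Feature Extraction 10.7.3.1, with the background subtracted and trends across the array removed, and no scaling between arrays. The deposited value table of the authors is in log2 units. The submitters' processing notes name Feature Extraction and limma, but the centring and normalization of the table are not stated and are unknown. Its column medians were 5.95, 5.96, 6.00 and 5.92 for skin KO 1 to 4, and 5.94, 5.92 and 5.92 for skin WT 1 to 3. The liver medians were 5.87, 5.84 and 5.78 for KO 1 to 3, and 5.79, 5.80 and 5.83 for WT 1 to 3. The fat medians were 5.83, 5.91, 5.80 and 5.76 for KO 1 to 4, and 5.86, 5.81, 5.83 and 5.82 for WT 1 to 4. The sorted columns of a tissue differed by at most 0.156 (skin), 0.158 (liver) and 0.162 (fat).

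The scanner values were read in R 4.3.3 with the data.table package (1.17.8). Spots of a probe were averaged, log2 was taken of the processed intensity, and the 75th percentile of each array was subtracted, so a value of 0 is that percentile. The array held 41174 probes without controls. Of the probes of a gene name, the one with the highest mean was used, and 9020 of 27373 gene names had more than 1 probe. Accessions of 27816 probes matched a RefSeq transcript, which gave 18468 genes their usual symbol. Probe positions are those of the files on mouse build mm9, and the exon or untranslated region under a probe was not analysed here. A gene was tested in a tissue when Feature Extraction set its probe well above background on at least 3 arrays of that tissue.

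The scanner file of fat WT 2 was left out. Its values correlated across probes with those of skin arrays (r from 0.863 to 0.914) more than with fat arrays (r from 0.725 to 0.766), and its r with its own column of the value table was 0.779 against at least 0.972 for the other 20 arrays. Genes are not independent replicates in these correlations. The fits were therefore of 20 arrays, with 4 KO and 3 WT in fat, where the plan had 21 arrays and 4 against 4. The file was used as deposited in an alternative only. No 2 arrays were duplicates, the highest r between any 2 being 0.986.

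KO was compared with WT in each tissue with limma 3.58.1 (linear model per gene, moderated errors, two-sided, Benjamini-Hochberg adjustment over the genes tested), and genes with an adjusted p below 0.05 were called. Differences in the KO effect between tissues were contrasts in 1 fit of group means over 20 arrays, over genes tested in either tissue. Overlaps of calls were tested with Fisher's exact test. Gene lists were tested with camera from limma with a preset correlation of 0.01 and adjusted over the lists of a tissue, with camera at an estimated correlation and fry beside it. Members were also counted with p adjusted over the list alone. Differences of list means between groups were tested by an exact permutation test, two-sided, whose smallest possible p is 0.0286 for 4 against 3 and 0.1 for 3 against 3. Where no array of a group was well above background, the fold is a bound, written as at least that fold, set by the background level. Errors are SD unless given as SE.

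Lists of pathway genes and of markers of the cell types a sample could hold were fixed before the data were examined, as were the thresholds, the other settings to try and the rule for naming genes. The lists were JNK pathway components, NRF2 targets and antioxidant enzymes, NADPH oxidase and other sources of reactive oxygen, p53 targets, ER stress, immediate-early genes, cytokines and chemokines, interferon response, acute phase, matrix, cell cycle, oxidative phosphorylation, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, bile acid synthesis, gluconeogenesis, xenobiotic metabolism, thyroid hormone response, circadian clock, male-biased and female-biased liver genes, thermogenic genes, keratinocyte differentiation, basal and activated keratinocytes, hair follicle, sebaceous gland, melanocyte, adipocyte, hepatocyte, macrophage, lymphocyte, endothelial, skeletal muscle, mesothelial, erythroid, and epididymis and testis markers. The rule named the JNK genes, up to 16 called genes of a tissue or, with under 10 called, the 5 higher and 5 lower with the smallest p, up to 4 members of a list, and up to 5 genes of each difference. Genes known only by a clone name were outside it. *A930038B10Rik* and the genes named for their place on a chromosome or as markers of another tissue were chosen after their values were seen.

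The other settings tried were normexp background correction with an offset of 50, quantile normalization, the authors' values (with fat WT 2), no filter or a filter on every array, the mean of all probes, limma with trend and robust priors, array weights, slide as a random block, slide as a fixed block (within tissues this also changed the fit to 1 of all arrays), the replicate number as a block, 1 fit of all arrays, a plain per-gene test, a threshold of 0.1, and leaving out each array. Further settings were chosen after seeing the data. They left out the dim skin arrays, the liver arrays with high *Lor* (a keratinocyte gene) or the fat arrays with epididymal transcripts. Others of these included or dropped fat WT 2, or used the authors' values for the lists. The arrays lay on 6 slides, and only slide 3 held both genotypes of a tissue (fat KO 2 and WT 4), so in skin and liver the slide and the genotype overlap.

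The procedure was tested on simulated data, normal values around each gene's real mean with its real residual SD and known shifts in the KO arrays. At a shift of log2 2, 63.6% of shifted genes were called in skin, 86.4% in liver and 74.2% in fat, and at log2 1 the shares were 20.6%, 35.3% and 47.1%. Calls of unshifted genes numbered 5, 14 and 9 in simulations of 13493, 13298 and 15028 genes. In the same way, 72%, 64% and 63% of differences between tissues of log2 2 were called for skin minus liver, skin minus fat and liver minus fat. With genes simulated as independent, the list test called the 1 shifted list and 0 of 20 unshifted lists in each tissue. Estimated correlations in the real lists ran from -0.0416 (ER stress in liver) to 0.936 (hepatocyte markers in fat). The simulation therefore does not give the rate of false calls for correlated lists. From 38.9% (skin KO 1) to 57.2% (fat KO 2) of probes were well above background on the 20 arrays used, and the number of arrays limits the precision.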

Results

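The series asked how the loss of JNK1, a stress-activated kinase, bears on metabolic protection from long-term high-fat feeding and on oxidative damage in skin. Expression was measured in skin (4 KO and 3 WT arrays), liver (3 and 3) and epididymal fat (4 KO and 3 WT arrays used of 4 and 4 in the files). Of 41174 probes, 38.9% (skin KO 1) to 57.2% (fat KO 2) were well above background on an array. Values are log2 intensity relative to the 75th percentile of the array, and differences are KO minus WT on the log2 scale. The WT arrays are the control group of every comparison.

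The targeted gene *Mapk8*, which encodes JNK1, was lower in KO fat, at -3.43 ± 0.30 (SD, n = 4) against -1.03 ± 0.11 (SD, n = 3) in WT fat. The difference of -2.40 (SE 0.189) passed the test in limma (adjusted p = 0.0214), and all 4 KO arrays lay below all 3 WT arrays. In liver the values were -4.20 ± 0.80 (SD, n = 3) and -1.83 ± 0.20 (SD, n = 3), a difference of -2.37 (SE 0.384) that did not pass (adjusted p = 0.224). In skin the gene was well above background on 0 of 4 KO arrays and 2 of 3 WT arrays, at least 1.06-fold lower in KO and not tested. In KO the probe was still well above background on 3 of 4 fat arrays and 1 of 3 liver arrays. It lies on chromosome 14 from 34204748 to 34204807 (mm9), and the labels do not state which part of the gene was removed. Another *Mapk8* probe, starting at 34194834, differed by -2.45 in fat and -1.40 in liver. The remaining *Mapk8* probes were well above background on at most 1 array of a tissue and differed by -1.135 to 0.175 in fat. *Mapk9*, which encodes the related kinase JNK2, differed by 0.03 in skin, -0.04 in liver and -0.02 in fat and passed in none of these (adjusted p = 0.952, 1.0 and 0.987). *Mapk10*, the third JNK gene, was well above background on 1 of the 20 arrays, a fat KO array, and was not tested. The *Mapk8* call in fat ended in 11 of 22 alternatives, with adjusted p from 0.00253 to 1.0.

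**Figure D1:**
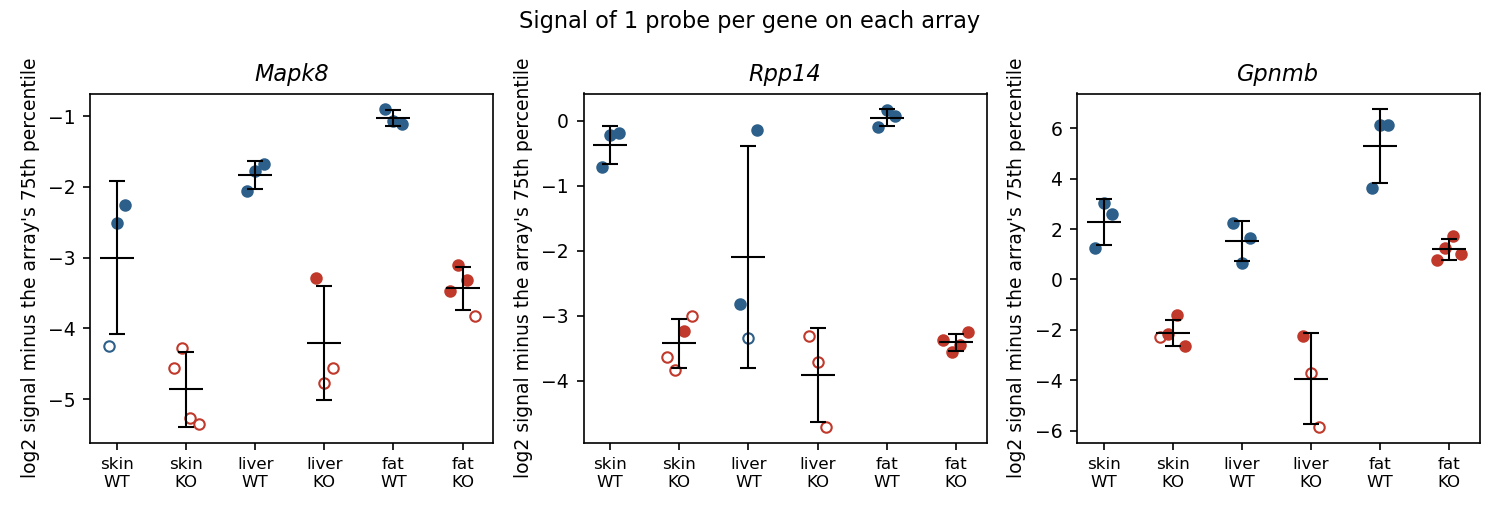
Log2 intensity relative to the 75th percentile of the array for *Mapk8*, *Rpp14* and *Gpnmb* in skin, liver and fat, with 1 point per array, blue for WT and red for KO. Filled points are well above background and open points are not, and bars show mean ± SD. *Mapk8* in fat averages -3.43 in KO and -1.03 in WT, and *Gpnmb* in skin averages -2.13 in KO and 2.29 in WT.

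The skin comparison asked what the loss of JNK1 changed in the tissue whose oxidative damage the series names. *Rpp14*, which encodes a subunit of ribonuclease P, fell to -3.43 ± 0.37 (SD, n = 4) in KO skin from -0.38 ± 0.30 (SD, n = 3) in WT skin, a difference of -3.05 (SE 0.260; adjusted p = 0.0239). *Gpnmb*, which encodes a membrane glycoprotein of macrophages and melanocytes, fell to -2.13 ± 0.52 (SD, n = 4) from 2.29 ± 0.92 (SD, n = 3), a difference of -4.42 (SE 0.448; adjusted p = 0.0460). All 4 KO arrays lay below all 3 WT arrays for both genes. The *Rpp14* probe lies on chromosome 14 from 8924219 to 8924278 and the *Gpnmb* probe on chromosome 6 from 49006386 to 49006445. These 2 genes were the ones called by limma among 13496 tested, 0 were higher, and a plain per-gene test called 0. At an unadjusted p below 0.05 there were 378 higher and 700 lower genes, against 674.8 of either sign by chance. The groups did not overlap for 11.9% of genes, against 5.71% by chance, and the median difference of all genes was -0.10. No gene was called without KO 1, KO 2, KO 3 or WT 3 (0 each), without the dim arrays KO 1 and WT 1 (0) or with quantile normalization (0), and 32 were called without WT 2 (30 higher and 2 lower). The adjusted p ranged from 8.55e-05 to 0.375 for *Rpp14* and from 1.41e-04 to 0.613 for *Gpnmb* over 20 alternatives each.

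Hair keratin genes had the highest values of KO over WT in skin, without passing over all genes (adjusted p = 0.151). *Krtap21-1*, *Krtap19-2* and *Krtap19-4*, which encode proteins of the hair shaft, differed by 5.48 (SE 0.827), 6.30 (SE 1.01) and 5.92 (SE 0.946). Probes for such near-identical genes can bind transcripts of their relatives. *Spink12*, a protease inhibitor gene, was at least 17.4-fold higher and *Dio3*, which encodes an enzyme that inactivates thyroid hormone, at least 3.52-fold higher. The defensin genes *Defb8* and *Defb3* differed by -1.36 (SE 0.180) and -1.28 (SE 0.215), and *Asb4* by -1.31 (SE 0.225), also with adjusted p = 0.151.

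The hair follicle list rose together in KO skin, with all 28 tested members positive and a median of 4.10 (adjusted p = 1.23e-43 by camera, and adjusted p = 0.595 with an estimated correlation). Adjusted over the list alone 26 members passed, and over all genes 0 did. *Krt85*, *Krt25* and *Krt71*, which encode keratins of the hair shaft and its inner sheath, differed by 4.11, 4.14 and 3.74. The list mean was 4.92 ± 1.13 (SD, n = 4) in KO and 1.08 ± 1.09 (SD, n = 3) in WT (exact permutation p = 0.0286, the smallest 35 splits allow, and adjusted p = 0.331 over the 29 lists). The melanocyte list rose with it, with 7 of 8 members positive and a median of 1.86, or 1.35 with bounds (adjusted p = 1.44e-07, and adjusted p = 0.693 with an estimated correlation). Of its members 5 passed adjusted over the list alone, among them the pigment genes *Pmel* (3.02) and *Dct* (2.49) and *Tyrp1*, at least 6.05-fold higher. The cell cycle list rose, with 22 of 23 members positive and a median of 0.45 (adjusted p = 3.57e-05, and adjusted p = 0.747 with an estimated correlation), and 0 passed adjusted over the list alone. Its members include *Mki67* (1.28) and *Top2a* (1.12). The cell cycle median was 0.07 without the dim array KO 1 and 0.70 without KO 4.

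Markers of other cell types moved with these groups. Endothelial markers fell, with 15 of 16 negative and a median of -0.64 (adjusted p = 6.61e-05, and adjusted p = 0.747 with an estimated correlation), such as *Cldn5* (-0.74) and *Flt1* (-0.75). Skeletal muscle markers fell, with all 20 negative and a median of -0.69 (adjusted p = 6.82e-05, and adjusted p = 0.747 with an estimated correlation), such as *Actn3* (-1.18). Adipocyte markers fell, with 16 of 19 negative and a median of -0.53 (adjusted p = 7.05e-04, and adjusted p = 0.747 with an estimated correlation), such as *Aqp7* (-0.89) and *Slc2a4* (-0.86). Hepatocyte markers rose, with 11 of 14 positive and a median of 0.23 (adjusted p = 0.0284, and adjusted p = 0.747 with an estimated correlation). In these 4 lists, 0 members passed over all genes. Without the dim array KO 1 the medians were -0.40 for skeletal muscle, -0.35 for adipocyte and 0.56 for hepatocyte markers. The hepatocyte median was 0.46 without WT 1 and 0.10 without WT 2, and its call ended without KO 2 (adjusted p = 0.154), KO 4 (0.258) or WT 3 (0.422).

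Genes of oxidative stress defence, the subject the series names for skin, went both ways. Of 30 NRF2 targets and antioxidant enzymes 10 were positive and 20 negative, with a median of -0.15 (adjusted p = 0.755), and the values included *Gpx2* (1.88), *Gpx3* (-0.78), *Keap1* (-0.55) and *Sod1* (-0.50). NADPH oxidase and other sources of reactive oxygen had a median of -0.10 (adjusted p = 0.885) and p53 targets of -0.08 (adjusted p = 0.755). The keratinocyte lists were not called, with medians of 0.22 for differentiation genes (adjusted p = 0.0528) and 0.20 for basal and activated genes (adjusted p = 0.0509). Single members stood apart, such as *Sprr2d* (3.97), *S100a9* (4.13) and *Il1b* (3.11), a cytokine gene of a list that was not called (adjusted p = 0.474). Adjusted over the list alone, *Defb3*, *Gpnmb*, *Ucp3* (-1.01) and *Ahsp* (3.92) passed in 4 lists that were not called.

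The other skin lists were not called. Medians were -0.49 for thermogenic genes (adjusted p = 0.0509), -0.28 for fatty acid oxidation (0.0528), -0.31 for macrophage markers (0.0983), -0.17 for oxidative phosphorylation (0.136), -0.27 for interferon response (0.159) and -0.26 for thyroid hormone response (0.162). They were -0.01 for ER stress (adjusted p = 0.230), -0.39 for matrix genes (0.230), -0.31 for immediate-early genes (0.232), -0.55 for clock genes (0.298), -0.28 for fatty acid synthesis (0.339) and -0.55 for erythroid markers (0.508). The rest were JNK pathway components at -0.15 (adjusted p = 0.755), lymphocyte markers at -0.16 (0.870), cholesterol synthesis at -0.19 (0.897) and sebaceous gland markers at -0.17 (0.936). For ER stress, cytokine, p53 and sebaceous gland genes the test pointed up against a median at or below 0, and for erythroid markers the mean of 0.16 had the opposite sign of the median. With an estimated correlation camera called 0 of 29 skin lists, fry called 0, and 12 had an unadjusted camera p below 0.05.

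**Figure D2:**
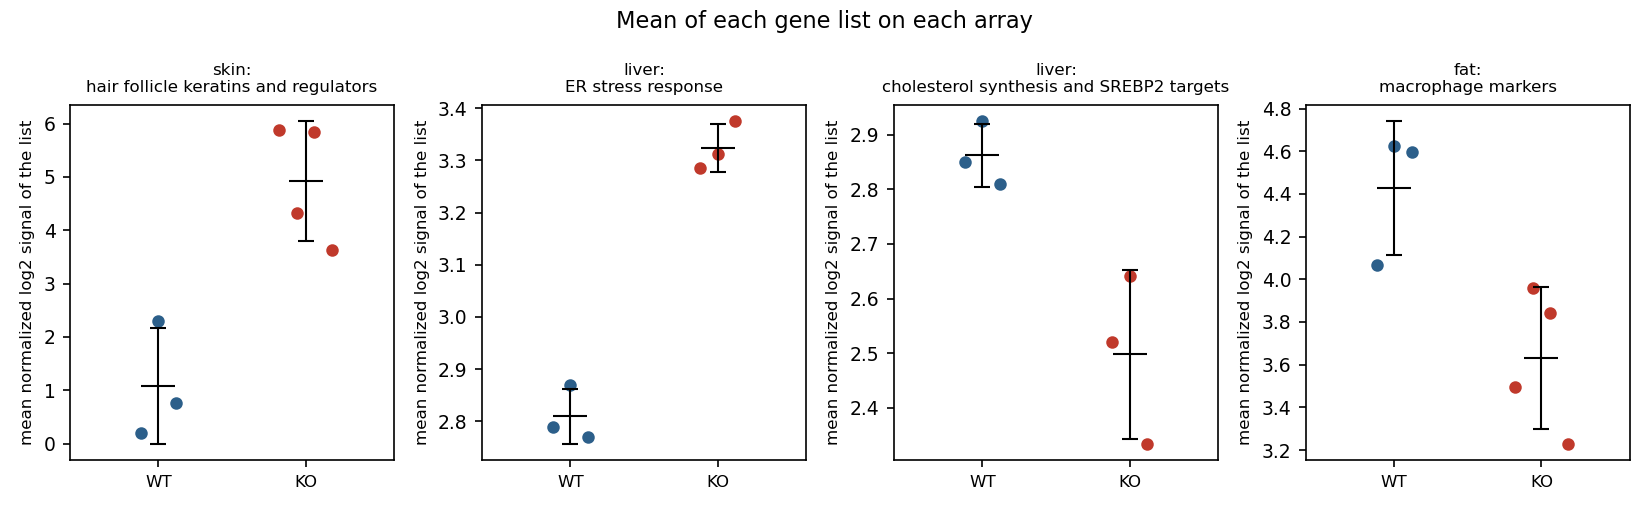
Mean log2 intensity of the members of 4 lists on each array, with 1 point per array, blue for WT and red for KO, and bars for mean ± SD. Hair follicle genes in skin average 4.92 in KO and 1.08 in WT, ER stress genes in liver 3.32 and 2.81, cholesterol synthesis genes in liver 2.50 and 2.86, and macrophage markers in fat 3.63 and 4.43.

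The liver comparison asked what the loss of JNK1 changed in a main organ of lipid and glucose metabolism. *Gdf10*, which encodes a growth factor of the BMP family, fell by 2.13 (SE 0.146; adjusted p = 0.0127), with all 3 KO arrays below all 3 WT arrays. *Lrit1*, which encodes a leucine-rich repeat membrane protein, was at least 16.8-fold lower (adjusted p = 0.0185) and the transcript *A930038B10Rik* at least 14.7-fold lower (adjusted p = 0.00638), again in all 3 KO arrays. These were the 3 genes called among 13301 tested. Their probes all lie on chromosome 14, starting at 34748161 (*Gdf10*), 37878039 (*Lrit1*) and 35579050 (*A930038B10Rik*), near *Mapk8*. By limma 0 genes were higher, a plain per-gene test called 0, and at an unadjusted p below 0.05 there were 325 higher and 487 lower genes, against 665.05 of either sign by chance. The groups did not overlap for 11.3% of genes, against 10% by chance. No gene was called without KO 3, WT 1 or WT 2 (0 each), 27 were called without WT 3 (24 higher and 3 lower), and 20 without the arrays KO 1, KO 2 and WT 3 (14 higher and 6 lower), which leaves KO 3 as the 1 KO array, assumed to vary like the WT arrays. The arrays left out had high *Lor*, a keratinocyte gene, at 3.22, 5.25 and 4.72 against -0.51, -0.36 and 0.52 on WT 1, WT 2 and KO 3. *Krt10*, a keratin gene of the epidermis, did not rise with it, at 0.31, 0.20 and 0.02 against 0.18, 0.20 and 0.33. The muscle gene *Ckm* was highest on the arrays left out, at -0.31, -1.77 and -1.04 against -2.75, -5.49 and -5.62. *Myh4*, another muscle gene, was at -0.01, -2.76 and 0.49 against -1.46, -5.30 and -5.27. Transcripts of other tissue may thus be present on these arrays. Skin tissue in these samples is not shown, since *Krt10* did not rise.

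Other liver genes with small p did not pass. *Reg2*, a secreted lectin gene, was at least 6.72-fold higher (adjusted p = 0.112), and *Arntl*, a core clock activator, differed by 1.98 (adjusted p = 0.122). *Pdia4*, which encodes an enzyme of protein folding, differed by 0.91 (adjusted p = 0.209) and *Clpx* by 1.15 (adjusted p = 0.220), and *Akap6* was at least 2.24-fold higher. Lower values were those of *Bcl7c* at -2.18 and *Slc5a6*, a vitamin transporter gene, at -1.49 (adjusted p = 0.0981 each) and *Ppp1r9a* at -1.63 (adjusted p = 0.112). *Gpnmb* differed by -5.46 (SE 0.877; adjusted p = 0.220).

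The ER stress list rose in KO liver, with 17 of 20 members positive and a median of 0.39 (adjusted p = 7.88e-12, and adjusted p = 0.0363 with an estimated correlation). It was the 1 list called by camera with an estimated correlation and by fry (adjusted p = 0.00295). Adjusted over the list alone 8 members passed, among them the chaperone and secretion genes *Pdia4* (0.91), *Creld2* (1.27) and *Manf* (1.02) and the amino acid synthesis gene *Asns* (1.23). The list mean was 3.32 ± 0.05 (SD, n = 3) in KO and 2.81 ± 0.05 (SD, n = 3) in WT, with an exact permutation p of 0.1, the smallest 3 against 3 arrays allow (adjusted p = 0.54 over the 27 lists).

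Lipid synthesis genes fell in KO liver. For cholesterol synthesis and SREBP2 targets 20 of 21 members were negative, with a median of -0.37 (adjusted p = 3.05e-08, and adjusted p = 0.389 with an estimated correlation), such as *Sqle* (-0.89), *Stard4* (-0.56) and *Msmo1* (-0.53). For fatty acid and triglyceride synthesis 16 of 19 were negative, with a median of -0.20 (adjusted p = 0.0164, and adjusted p = 0.649 with an estimated correlation), such as *Thrsp* (-0.92) and *Fads2* (-0.64). Bile acid synthesis and sterol transport rose, with 12 of 15 positive and a median of 0.29 (adjusted p = 0.0312, and adjusted p = 0.649 with an estimated correlation), including *Nr0b2* (0.84), a repressor of that pathway, and *Cyp8b1* (0.58). In these 3 lists 0 members passed over all genes. Without KO 3 the calls of fatty acid synthesis (median 0.01; adjusted p = 0.377) and of bile acid synthesis (median 0.09; adjusted p = 0.377) ended. The first also ended without WT 1 (adjusted p = 0.0521) and had a median of -0.38 without KO 2, and the second also ended without WT 3 (adjusted p = 0.101). Fatty acid oxidation was not called (median -0.05; adjusted p = 0.116), with *Cpt1a* at -0.53 and *Ppara* at -0.68.

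Sex-biased liver genes moved apart. Female-biased genes fell, with all 14 negative and a median of -0.34 (adjusted p = 1.28e-04, and adjusted p = 0.461 with an estimated correlation), and *Tox* (-0.67), *Cyp17a1* (-0.71) and *Acot3* (-2.08) passed adjusted over the list alone. Male-biased genes rose, with 16 of 18 positive and a median of 0.35 (adjusted p = 2.18e-04, and adjusted p = 0.649 with an estimated correlation), and *Elovl3* (2.13) passed adjusted over the list alone. Both calls ended without KO 3, with medians of -0.14 for female-biased (adjusted p = 0.0519) and 0.15 for male-biased genes (adjusted p = 0.0534), and the female-biased median was -0.52 without KO 1 and -0.59 without WT 2. The clock list was called lower, with 11 of 14 members negative and a median of -0.54 (adjusted p = 0.00446, and adjusted p = 0.461 with an estimated correlation). Its members went both ways, and adjusted over the list alone 3 were higher, including *Arntl* (1.98) and *Nfil3* (1.07), and 4 lower, including the output genes *Dbp* (-2.04) and *Tef* (-1.16).

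Cell cycle genes fell, with 18 of 19 negative and a median of -0.46 (adjusted p = 2.00e-04, and adjusted p = 0.649 with an estimated correlation), such as *Mcm5* (-0.86). Interferon response genes fell, with 16 of 21 negative and a median of -0.17 (adjusted p = 0.00495, and adjusted p = 0.649 with an estimated correlation), such as *Usp18* (-0.94) and *Ifit3* (-0.79). Erythroid markers rose, with 5 of 6 positive and a median of 0.22 (adjusted p = 0.0351, and adjusted p = 0.649 with an estimated correlation), such as *Tspan33* (0.94). Acute phase genes rose, with 13 of 19 positive and a median of 0.19 (adjusted p = 0.0359, and adjusted p = 0.649 with an estimated correlation), such as *Fga* (0.68). Without KO 3 the calls of cell cycle (median -0.19; adjusted p = 0.173), interferon (median -0.05; adjusted p = 0.57) and acute phase genes (adjusted p = 0.0997) ended. The cell cycle median was -0.75 without KO 2 and -0.27 without WT 1, and the interferon median -0.33, -0.11 and -0.29 without KO 2, WT 2 and WT 3. The erythroid call ended without KO 2 (adjusted p = 0.0924) or WT 3 (0.311), and the acute phase call without KO 2 (0.0799), WT 1 (0.0664) or WT 3 (0.205). The liver lists were called on samples of which KO 1, KO 2 and WT 3 had high *Lor* and the highest *Ckm*, without a rise of *Krt10*.

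The remaining 15 liver lists were not called. Medians were -0.23 for matrix genes (adjusted p = 0.0991), -0.20 for immediate-early genes (0.116), -0.09 for macrophage markers (0.131), -0.09 for cytokines (0.321), 0.09 for hepatocyte markers (0.386), 0.06 for xenobiotic metabolism (0.386) and 0.16 for lymphocyte markers (0.386). They were 0.04 for endothelial markers (adjusted p = 0.547), -0.07 for thyroid hormone response (0.581), -0.15 for gluconeogenesis (0.594), 0.03 for JNK pathway components (0.609), 0.02 for NRF2 targets (0.847), -0.01 for oxidative phosphorylation (0.953), -0.04 for NADPH oxidase genes (0.963) and 0.00 for p53 targets (0.970). Among them *G6pc*, which encodes the last enzyme of glucose release, was at 0.70. For JNK pathway, NRF2, NADPH oxidase and p53 genes the mean had the opposite sign of the median (-0.16, -0.03, 0.04 and -0.02), and for oxidative phosphorylation the test pointed up. *Mapk8* and *Gpnmb* passed adjusted over the list alone in 2 of these lists.

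**Figure D3:**
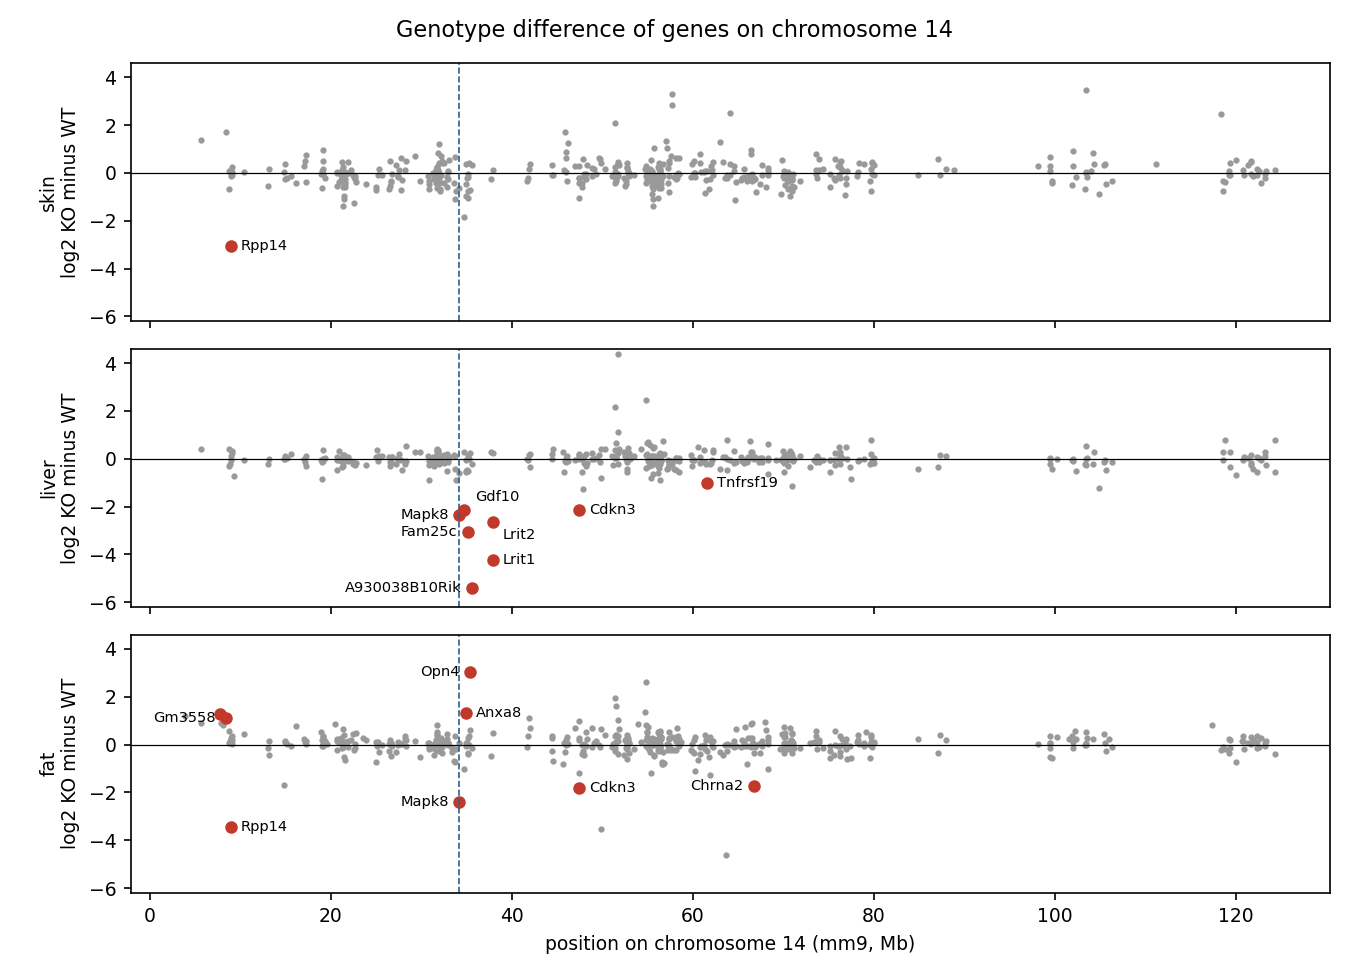
Difference of KO minus WT (log2) for every tested gene along chromosome 14 (position in Mb, mm9) in skin, liver and fat, with 1 point per gene. Red points have an unadjusted p below 0.001 and carry their symbol where the files give one, and the dashed line marks *Mapk8*. In liver 8 of 450 genes are red and all 8 are lower in KO, in fat 8 of 516 with 4 lower, and in skin 1 of 463.

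The fat comparison asked what the loss of JNK1 changed in the tissue that stores the dietary fat. *Rpp14* fell by 3.45 (SE 0.136; adjusted p = 2.95e-04) and *Mapk8* by 2.40 (SE 0.189; adjusted p = 0.0214), in all 4 KO arrays against all 3 WT arrays. These were the 2 genes called among 15246 tested, 0 were higher by limma, and a plain per-gene test called 1. At an unadjusted p below 0.05 there were 678 higher and 522 lower genes, against 762.3 of either sign by chance, and the groups did not overlap for 8.98% of genes, against 5.71% by chance. On slide 3, which held KO 2 and WT 4, *Rpp14* differed by -3.63, *Mapk8* by -2.0 and *Gpnmb* by -4.88. Without WT 4 the count was 21, without KO 1, KO 3 or WT 3 it was 1 each, with the scanner file of WT 2 included it was 0, and without WT 1, WT 3 and KO 2 it was 0, with WT 4 as the 1 WT array left, assumed to vary like the KO arrays. The 3 arrays left out had the highest values of *Crisp1*, an epididymal gene, at 5.39 on WT 1, 4.94 on WT 3 and -1.24 on KO 2. It was at -1.84 on WT 4 and at -6.07, -4.85 and -5.81 on KO 1, KO 3 and KO 4. On WT 4 it was still well above background, and on KO 1, KO 3 and KO 4 it was not. Leaving out the 3 arrays thus does not remove all epididymal transcripts.

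Other fat genes with small p did not pass (adjusted p = 0.319). *Akr1b7*, an aldo-keto reductase gene also active in the male reproductive tract, differed by -10.31 (SE 1.39), *Gpnmb* by -4.11 (SE 0.622), *Asb4* by -2.61 and *Homer2* by -1.26. On slide 3 these differed by -6.27, -4.88, -2.35 and -1.63. *Aspg* (1.54) and *Anxa8* (1.33) had higher values, and *Opn4*, *Gzma* and *Ccdc142* were at least 2.52-fold, 1.67-fold and 1.47-fold higher. On slide 3 these 5 differed by 2.0, 1.78, 3.56, 0.79 and 1.32.

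Macrophage markers fell in KO fat, with 23 of 25 negative and a median of -0.59 (adjusted p = 2.16e-11, and adjusted p = 0.678 with an estimated correlation). Adjusted over the list alone 8 passed, among them *Gpnmb*, *Mmp12* (-2.15), an elastase gene of macrophages, and the integrin genes *Itgam* (-1.35) and *Itgb2* (-1.12). The list mean was 3.63 ± 0.33 (SD, n = 4) in KO and 4.43 ± 0.31 (SD, n = 3) in WT (exact permutation p = 0.0286, and adjusted p = 0.80 over the 28 lists), and differed by -0.64 on slide 3. NADPH oxidase and other sources of reactive oxygen fell, with 7 of 11 negative and a median of -0.40 (adjusted p = 0.0270, and adjusted p = 0.678 with an estimated correlation; difference of list means -0.29 on slide 3). Its members *Cybb* (-1.07) and *Ncf1* (-0.88) encode parts of the phagocyte oxidase. Matrix genes fell, with 18 of 24 negative and a median of -0.18 (adjusted p = 0.0406, and adjusted p = 0.678 with an estimated correlation; difference of list means -0.43 on slide 3), such as *Ccn2* (-0.97) and *Acta2* (-0.63). The NADPH oxidase call ended without KO 1 (adjusted p = 0.197) or WT 4 (0.125), and its median was -0.64 without WT 1. The matrix call ended without KO 1 (adjusted p = 0.280), KO 2 (0.0807), KO 3 (0.0527), WT 1 (0.137) or WT 4 (0.269), and its median was -0.30 without KO 4.

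Blood and vessel markers rose in KO fat. Erythroid markers had 7 of 8 positive and a median of 0.81 (adjusted p = 6.26e-04, and adjusted p = 0.678 with an estimated correlation; difference of list means 0.87 on slide 3), and 5 passed adjusted over the list alone, including *Alas2* (0.99) and *Hba-a1* (0.63). Lymphocyte markers had 18 of 21 positive and a median of 0.45 (adjusted p = 0.00336, and adjusted p = 0.678 with an estimated correlation; difference of list means 0.73 on slide 3), and *Gzma* passed adjusted over the list alone. Endothelial markers had all 16 positive and a median of 0.28 (adjusted p = 0.00432, and adjusted p = 0.678 with an estimated correlation; difference of list means -0.07 on slide 3), such as *Egfl7* (0.43). Acute phase genes rose, with 14 of 17 positive and a median of 0.83 (adjusted p = 0.0406, and adjusted p = 0.678 with an estimated correlation; difference of list means 2.11 on slide 3), such as *Saa3* (1.19). Liver markers moved with this list, the hepatocyte list mean being 1.24 on KO 2, 0.55 on KO 4 and 0.36 on WT 3, where acute phase means were 1.19, 1.03 and 0.44, and -1.90 on KO 1 and -3.12 on WT 4, where they were -0.26 and -0.93. The acute phase call ended without KO 2 (adjusted p = 0.315), KO 4 (0.122), WT 1 (0.0980) or WT 4 (0.387). The lymphocyte call ended without KO 2 (adjusted p = 0.163) and its median was 0.28 without WT 3, and the endothelial call ended without KO 1 (0.156) or WT 3 (0.0909).

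Markers of neighbouring tissue moved with these lists in fat. Epididymis and testis markers fell, with 7 of 8 negative and a median of -1.38 (adjusted p = 0.00659, and adjusted p = 0.678 with an estimated correlation; difference of list means 2.87 on slide 3), such as *Crisp1* (-7.32) and *Spink8* (-6.46). For endothelial and epididymal markers the direction did not hold on slide 3. Skeletal muscle markers fell, with 11 of 16 negative and a median of -0.35 (adjusted p = 0.0401, and adjusted p = 0.678 with an estimated correlation; difference of list means -0.32 on slide 3). Without WT 1, WT 3 and KO 2 the lymphocyte list pointed lower (adjusted p = 0.990), with WT 4 as the 1 WT array left. The epididymal call ended without KO 4 (adjusted p = 0.0825) or WT 1 (0.0602), with a median of -2.26 without KO 2. The skeletal muscle call ended without KO 2 (adjusted p = 0.0639), KO 4 (0.389), WT 1 (0.0913) or WT 3 (0.133), with a median of -0.69 without KO 1. The liver gene *Alb* ranged from 0.04 to 4.84 over the fat arrays.

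The other 19 fat lists were not called. Medians were -0.10 for cell cycle genes (adjusted p = 0.0869), -0.13 for mesothelial markers (0.114), -0.03 for cholesterol synthesis (0.160), 0.89 for hepatocyte markers (0.160), -0.09 for immediate-early genes (0.160), 0.11 for interferon response (0.265) and 0.16 for thyroid hormone response (0.265). They were 0.02 for JNK pathway components (adjusted p = 0.301), -0.07 for thermogenic genes (0.355) with *Ucp1* at -1.83, -0.04 for ER stress (0.395), 0.07 for NRF2 targets (0.434), -0.04 for clock genes (0.449), 0.26 for gluconeogenesis (0.449) and 0.23 for fatty acid synthesis (0.616) with *Mlxipl* at 0.93. Oxidative phosphorylation was at 0.06 (adjusted p = 0.631), fatty acid oxidation at 0.08 (0.631), p53 targets at -0.01 (0.811), adipocyte markers at 0.00 (0.811) and cytokines at 0.13 (0.811). For JNK pathway, ER stress and NRF2 genes the mean had the opposite sign of the median (-0.22, 0.02 and -0.06), and *Mapk8* passed adjusted over the list alone. With an estimated correlation camera called 0 of 28 fat lists, fry called 0, and 11 had an unadjusted camera p below 0.05.

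Whether the KO effect differed between tissues was tested directly. Skin and liver differed for 24 of 14820 genes, 23 with the more positive effect in skin, and 12 of the 24 carry keratin or keratin-associated symbols. *A930038B10Rik* differed by 5.22 (adjusted p = 4.53e-04), *Reg2* by -4.74 (adjusted p = 0.0187), *Flrt3*, an adhesion gene, by 3.17 (1.19 in skin and -1.98 in liver; adjusted p = 0.0187), *Rgs16*, a regulator of G protein signalling, by 2.38 (adjusted p = 0.0311) and *Lrit2* by 2.90 (adjusted p = 0.0325). Skin and fat differed for 68 of 16087 genes, 64 with the more positive effect in skin, of which 35 of the 68 carry keratin or keratin-associated symbols and 19 are in the hair follicle list. *Akr1b7* differed by 10.20, *Krtap19-4* by 6.39, *Krtap21-1* by 5.58, *Arg2*, an arginase gene, by 4.56 (1.08 in skin and -3.48 in fat) and *Ccn4* by 4.21 (1.71 and -2.50), each with adjusted p = 0.0204. Liver and fat differed for 9 of 15965 genes, 4 higher and 5 lower in liver. *A930038B10Rik* differed by -5.26 (adjusted p = 4.35e-04), *Rgs16* by -2.82 (-2.24 in liver and 0.59 in fat; adjusted p = 0.00793), and *Reg2* by 4.62, *Arg2* by 4.77 and *Akr1b7* by 9.33 (adjusted p = 0.0198 each). Most of these named genes were too near background to be tested in 1 of the tissues compared. *A930038B10Rik* and *Reg2* were tested in liver only, and *Lrit2* and *Akr1b7* were not tested in skin. *Flrt3* and *Arg2* were not tested in liver, nor *Krtap19-4* and *Krtap21-1* in fat. The fitted difference of such a gene is no bound. The skin and fat count was 0 without skin WT 1, 3 without skin WT 3 and 2 without fat WT 3. Others of the 68 genes fell in KO fat, such as *Crisp1* (-7.32), *Fxyd4* (-6.86) and *Cldn7* (-4.41). *Crisp1* is an epididymal gene and was high on fat WT 1 and WT 3. Transcripts of neighbouring tissue may therefore add to this count, which was not tested. The skin and liver count ranged from 2 to 98 when single arrays were left out. Without liver WT 3, skin and liver differed for 15 genes with the more positive effect in skin and 24 with the more negative, and liver and fat for 27 and 9. Without fat WT 4, liver and fat differed for 45 and 5.

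*Rpp14* was the 1 gene called in the same direction in 2 tissues, skin and fat, against 0.000158 expected by chance (Fisher's exact test, two-sided p = 1.58e-04), and the overlap was 0 with quantile normalization. At an unadjusted p below 0.01, 6 genes were lower in both skin and liver (0.438 expected; exact p = 4.42e-06), 5 in skin and fat (0.536 expected; exact p = 1.92e-04) and 9 in liver and fat (1.08 expected; exact p = 1.28e-06). The counts of genes higher in both were 0, 4 (0.427 expected; exact p = 8.63e-04) and 2 (0.313 expected; exact p = 0.0390). Genes are not independent replicates in these tests. Across genes, the differences correlated with r of 0.0134 (skin and liver), -0.0370 (skin and fat) and 0.0889 (liver and fat).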

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

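The counts of other splits were planned, and the tests on dim arrays, other cells and slides for the hair follicle genes were chosen after the result was seen.

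The KO effect differed between skin and fat for 68 genes. Of 100 regroupings 1 (the real one) gave as many, and the highest other gave 64, so chance is unlikely but not excluded. The regroupings took no account of slides, and no gene was called with slide as a fixed block or without skin WT 1. Epididymal transcripts on fat WT 1 and WT 3 may add to the 68, which was not tested. For skin and liver the KO effect differed for 24 genes, where chance cannot be excluded, since 9 of 100 regroupings gave as many and the highest other gave 118. For liver and fat it differed for 9 genes, where chance cannot be excluded either, since 16 of 100 gave as many and the highest other gave 39. Regroupings with several times the real count may reflect a structure of the samples other than genotype, which was not tested.

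Genes met this test of a difference between tissues with the following values. In skin minus liver these were *A930038B10Rik* (5.22), *Reg2* (-4.74), *Flrt3* (3.17), *Rgs16* (2.38) and *Lrit2* (2.90). In skin minus fat they were *Akr1b7* (10.2), *Krtap19-4* (6.39), *Arg2* (4.56), *Ccn4* (4.21) and *Krtap21-1* (5.58). In liver minus fat they were *A930038B10Rik* (-5.26), *Rgs16* (-2.82), *Reg2* (4.62), *Arg2* (4.77) and *Akr1b7* (9.33).

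The keratin genes among these differences belong to the higher hair follicle genes in KO skin. The dim arrays KO 1 and WT 1 are argued against as the source, since the list means still differed by 3.07 without them. A smaller share of muscle, fat and vessel cells would raise epithelial and gland genes alike, but the hair follicle median lay at least 2.59 pooled SD above those of 3 such lists. The slides cannot be told apart from genotype, since no slide held both genotypes of skin and the exact permutation p over slide means was 0.1, the smallest 2 against 3 slides allow. A larger share of growing follicles in KO skin, from the genotype, the hair cycle or the site of sampling, may account for it and was not tested.

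A sample far from the others of its group was found for 4 of 81 measures, and chance gives about 1 in 20. The measures were list means, gene values and array quality of the skin KO and fat KO groups only. They are not independent, since they come from the same arrays. The list means concerned were NRF2 targets on skin KO 3 (3.57), cholesterol synthesis on skin KO 1 (3.28), ER stress on fat KO 4 (2.30) and fatty acid synthesis on fat KO 4 (3.16).

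The scanner file of fat WT 2, outside every comparison, had *Krt10*, a keratin gene of the epidermis, at 8.55, against -0.60 to -0.17 on the other fat arrays and 8.62 to 9.18 on the skin arrays.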

How the results depend on the processing

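Settings that left out or included named sets of arrays, and the authors' values for the lists, were chosen after seeing the data; all other alternatives and the splits were planned. The cause of a change was not tested unless said.

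In skin, 2 called genes became 0 with quantile normalization, no filter, the every-array filter, the per-gene test or without the dim arrays, 1 with the authors' values or slide as a random block, 131 in 1 fit of all arrays (114 higher, 17 lower) and 1700 with array weights (618 higher, 1082 lower), which stopped before convergence. Leaving out 1 array gave 0 to 32 (0 without KO 1, KO 2, KO 3 or WT 3, 32 without WT 2, 30 of them higher). In liver, 3 became 11 with normexp, 5 with the authors' values or a threshold of 0.1, and 1 with no filter or the every-array filter. The count was 10 with array weights or trend and robust priors, 20 in 1 fit of all arrays (2 higher, 18 lower), and 0 by the per-gene test. Without the liver arrays with high *Lor* 1 KO array (KO 3) is left, and without the epididymal arrays 1 WT array (WT 4). The lone sample is then assumed to vary like the other group. On fat WT 4 *Crisp1* was still well above background, so some epididymal transcripts remain. Leaving out 1 array gave 0 to 27 (0 without KO 3, WT 1 or WT 2, 27 without WT 3, 24 of them higher). In fat, 2 became 1 with the authors' values including WT 2 (2 without it), no filter, the every-array filter or the per-gene test, 57 in 1 fit of all arrays (6 higher, 51 lower), and 0 without the epididymal arrays or with the WT 2 file. Leaving out 1 array gave 1 to 21 (1 without KO 1, KO 3 or WT 3, 21 without WT 4). Slide as a fixed block was fitted within 1 fit of all arrays, so 2 settings changed. It gave 0 genes in skin, 5 in liver and 1 in fat, against 131, 20 and 57 in that fit without the block. The overlap of 1 gene became 0 with quantile normalization. Slide as a random block could not be fitted in liver. The called genes kept their direction in every alternative.

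For genes, the real split gave the most calls in skin (2, highest other split 1, with 1 of 35 splits as large) and fat (2, highest other 0, with 1 of 35). Chance is thus unlikely but not excluded, since this is the smallest share that 35 splits allow. In fat 1 of the 2 genes is *Mapk8*, the targeted gene. For lists chance cannot be excluded in skin (7, highest other 15, with 23 of 35) or fat (9, highest other 12, with 12 of 35). In liver the 10 splits are too few, with 3 genes against a highest other of 10, in the split of KO 1, KO 2 and WT 3 (2 splits as large), and 11 lists against 14 (2 splits as large).

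The skin minus liver count of 24 became 5 with normexp or the every-array filter, 64 with quantile normalization, 62 with the authors' values (fat WT 2 in the fit), 3 with no filter, 4 with slide as a fixed block, 237 with array weights and 69 at a threshold of 0.1. It was 2 to 98 without 1 array: 2 without skin KO 1, skin KO 3, liver KO 1, liver KO 3 or liver WT 1, 3 without skin WT 1, skin WT 3 or fat WT 4, 5 without fat KO 2, fat KO 3 or fat WT 1, 6 without liver KO 2 or liver WT 2, 14 and 15 without fat KO 1 and KO 4, 39 without liver WT 3 (15 higher, 24 lower), 83 without skin WT 2 and 98 without skin KO 4. The skin minus fat count of 68 became 104 with the authors' values including fat WT 2, 43 with no filter, 3 with the every-array filter or the WT 2 file, 0 with slide as a fixed block, 334 with array weights and 128 at 0.1, and 102 with normexp was 66 higher and 36 lower. It was 0 to 142 without 1 array: 0 without skin WT 1, 2 without fat WT 3, 3 without skin WT 3, 23 and 26 without skin KO 1 and KO 3, 24 without fat WT 1, 27, 32, 37 and 41 without fat KO 3, KO 1, KO 4 and KO 2, 39 and 44 without liver WT 3 and WT 1, 122 without fat WT 4 and 142 without skin KO 4. The liver minus fat count of 9 became 15 with quantile normalization (4 higher, 11 lower), 2 with the every-array filter, slide as a fixed block or the WT 2 file, and 78 with array weights. It was 2 to 50 without 1 array: 2 without liver WT 1 or WT 2, 3 and 4 without liver KO 1 and KO 2, 4 without fat KO 3, KO 4 or WT 1, 5 without fat KO 1, 36 without liver WT 3 (27 higher, 9 lower) and 50 without fat WT 4 (45 higher, 5 lower).

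Called lists numbered 0 in skin, 1 in liver (ER stress) and 0 in fat with an estimated correlation, and the same with fry. In skin 7 became 16 with no filter, 11 with slide as a fixed block in 1 fit of all arrays and 12 without the dim arrays, and 6 to 14 without 1 array (11 without KO 4, 14 without WT 1). In liver 11 became 5 with that block and fit, and 5 to 14 without 1 array (5 without KO 3). In fat it was 7 to 10 without 1 array. ER stress in liver stayed called in 16 of 16 alternatives, at an adjusted p of at most 0.0363. Directions turned for lymphocyte markers in skin (adjusted p = 6.68e-05), interferon response in liver (0.941) and skeletal muscle markers in fat (0.877) with slide as a fixed block in 1 fit of all arrays, for NRF2 targets in liver without the arrays with skin transcripts (0.0378, with 1 KO array left), for epididymal markers in fat with no filter (0.846) and for lymphocyte markers in fat without the epididymal arrays (0.990, with 1 WT array left).

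The replicate number as a block gave 0, 0 and 0 called genes in skin, liver and fat, 2, 73 and 6 for the differences in the order above, and 11, 10 and 8 lists. The numbers do not pair KO and WT arrays, since deviations from the group means on KO and WT arrays of equal number correlated across genes with r from -0.227 to 0.185.

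Signal over background set which genes were tested. *Mapk8* in skin and *Rpp14* in liver were too dim, and folds of genes at background in 1 group are bounds.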

Other observations

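The test of called genes on the chromosome of *Mapk8* was planned, and the tests at an unadjusted p of 0.01, on other probes, on macrophage markers and on clock genes were chosen after the result was seen.

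At an unadjusted p below 0.01, 24 genes differed in the same direction in at least 2 tissues, 18 lower and 6 higher in KO. Chromosome 14 held 6 of them, among them *Mapk8*, *Rpp14*, *Cdkn3*, a phosphatase gene of the cell cycle (-2.14 in liver and -1.81 in fat), and *Ccnb1ip1* (2.09 in skin and 1.93 in fat). Another probe of *Cdkn3* differed by -1.02 in liver and -0.03 in fat, so the fall in fat rests on 1 probe. Chromosome 6 held 4, *Gpnmb*, *Asb4*, *Gp9* and *Lrtm2*, with probes far apart, starting at 49006386, 5382886, 87729650 and 119265616. *Rpp14* in liver, where it was not tested, was at -2.81, -3.34 and -0.15 on WT 1 to 3 and at -3.31, -3.72 and -4.71 on KO arrays.

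DNA of another strain carried along with the targeted locus is a candidate explanation for the genes on chromosome 14. The called gene *Rpp14* lies there (Fisher's exact test, one-sided p = 0.0345, resting on 1 gene). So do 5 of 22 genes of the wider set without *Mapk8*, *Rpp14* among them, against 3.45% of 13609 genes (exact one-sided adjusted p = 0.0154). These 5 lie 13.2, 17.2, 25.3, 25.8 and 28.5 Mb from *Mapk8*. The test counted the whole chromosome and not distance from the locus. All 3 genes called in liver also lie on chromosome 14, near *Mapk8*, but were outside this set, which needed 2 tissues. At an unadjusted limma p below 0.001, 8 of 450 chromosome 14 genes differed in liver, all 8 lower in KO. In fat 8 of 516 did (4 lower), and in skin 1 of 463. For a further stretch on chromosome 6 the exact adjusted p of 0.170 leaves the question open. *Gpnmb* lay at least 6.48 SD below the median of the other macrophage markers in each tissue. An even loss of macrophages would lower the markers alike, so these values argue against it as the sole cause for *Gpnmb*. The SD is over marker genes, and *Gpnmb* was chosen for its fall. A loss of only some macrophages was not tested. A variant under the probes used stays open. Other probes of 8 genes showed a median of 0.351 of the difference (quartiles 0.129 and 0.884), but *Cdkn3* alone of these is placed on chromosome 14. *Rpp14*, *Ccnb1ip1* and *Gpnmb* had no other measured probe. The genes were picked for a small p at the probe used, which favours a low ratio. An effect of JNK1 itself on these genes was not tested, since the locus and its neighbours go with the genotype.

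Clock genes in liver may reflect the time of day at dissection, which the labels do not give. If the tissues of a group shared it, the 13 clock genes should move in their liver direction in the other tissues. The mean move was 0.447 ± 0.0988 (SE) in skin and 0.147 ± 0.0605 (SE) in fat, against 0.912 ± 0.166 (SE) in liver. The liver value is positive by construction, since the liver set the direction of each gene. The SE is over genes, which are not independent replicates. These values do not decide between a shared time of day and an effect of genotype, which cannot be told apart here because the times are unknown.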
